A study of Homo sapiens with 12 samples.

How the data were processed

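The series holds 12 RNA sequencing libraries of BJ cells, an established line of human skin fibroblasts. Per the labels the cells were at passage 12, called young here, or at passage 45, called old here. They carried an adenovirus without an insert (Track, called the empty virus), with wild-type MYOD or with MYOD Y30F, and were kept in low-serum differentiation medium with horse serum. MYOD is the transcription factor that turns fibroblasts into muscle cells, and Y30F replaces a tyrosine, a target of the ABL kinase in DNA damage signalling, by phenylalanine. Each of the 6 groups has 2 libraries, which the labels number as replicates. Nothing in the labels says that they are separate cultures, so the p-values measure the spread between these libraries only. Total RNA was extracted with Trizol and sequenced with Illumina kits.

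The deposited files hold, for each library, the read count of each of 63677 Ensembl gene identifiers, made by the authors with HTSeq 0.6.1p1 on genome build hg19/GRCh37, per the submitters' processing notes. The aligner, the annotation release and the strand setting are not given in the sources used here, so counts of genes that overlap on opposite strands, and of close paralogs, are less certain. The counts are whole numbers without normalization, and 5 special entries per file for reads without a gene were set apart. The deposited comparison of old with young cells is a DESeq2 table (version not given). The authors' deposited table gives a mean signal per gene, the mean over libraries of counts divided by size factors before deposit, per the file headers. Recomputing it from the counts showed that the libraries are the 4 with the empty virus. The authors' deposited table also gives a log2 fold change, which is shrunken, with its standard error, a score (the Wald statistic) and a p-value with its adjusted form. That table is used here only for side-by-side values with the same 4 libraries.

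Gene symbols were matched by identifier to a later GENCODE release on another genome build. No coordinates are therefore given. Of the identifiers, 52181 have a symbol, 42155 have a count in some library, and 39319 have both. All 37 genes of the mitochondrial genome are listed at 0 in every library, so their share is no measure of RNA quality here.

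Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 6 groups (minimum count 10, minimum total 15), which left 22213 genes. Libraries were scaled with TMM factors and fitted in 1 model with a mean per group, leaving 6 residual degrees of freedom. Each comparison is a quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided and with no fold threshold. The SE of a log2 fold change is its size over the square root of F. Where a group has only a few reads, this SE can be smaller than the counting error of the fold. Levels are TMM-scaled CPM (counts scaled to a common library total), given as mean ± SD over the 2 libraries of a group. The comparisons are old against young cells with the empty virus, wild-type MYOD and Y30F each against the empty virus at each age, and Y30F against wild-type MYOD at each age. A further pair are interactions: the wild-type effect in old cells minus that in young cells, and the same for Y30F minus wild-type.

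The comparisons, tests, gene lists, alternatives and the rule for named genes were set before the data were examined. The 21 lists are sarcomere, myogenic regulators and fusion, excitation-contraction coupling and synapse, muscle energy metabolism, DNA replication, mitosis, E2F and pocket protein factors, DNA damage signalling and repair, p53 targets, senescence-associated secretion, fibroblast matrix, smooth muscle and TGF-beta response, MYOD antagonists, interferon response, and heat shock and unfolded protein response, with markers of keratinocytes, endothelium, leukocytes, melanocytes and Schwann cells, adipocytes and neurons. Each was tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes, and again with a correlation estimated from the data. The p-values were adjusted over the lists within a comparison. Beside it stand fry, which asks whether a list moves on balance in one direction, and the number of members past the threshold over all genes and adjusted over the list alone. A list's score in a library is the mean log2 CPM of its members (prior count 2), centred per gene.

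Named genes are the 5 largest changes each way among called genes with a mean log2 CPM of at least 2 and no overlap between the groups (for an interaction, no such demand), MYOD1 left out (gains and losses called largest in the text are largest among these), then the 2 members of each pathway list with the smallest adjusted p, or up to 4 where a paragraph is about the list. A fixed set completes them: MYOD1, MYOG, MEF2C, CKM, MYH3, MYH8, CDKN1A, CDKN2A, CDKN2B, CDKN1C, LMNB1, HMGB2, MKI67, CCNA2, CDC6 and ABL1. Where the reference group of such a gene has no reads, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 reads the ratio is given with its 95% interval for counts (exact binomial, Clopper-Pearson). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A list's median is also given with such genes at their bound, and for an interaction over the members with more than 3 counts in each group.

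The alternatives were RLE size factors, total counts as the only scaling, no filter, a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, an absolute log2 fold change of at least 1, all libraries thinned to the smallest, and leaving out each library. Recovery was checked on simulated counts, drawn from each gene's mean over the 12 libraries with the same spread in all groups. Changes were placed in genes with a mean of at least 2 CPM. At log2 1, the test recovered 74% for wild-type MYOD in young cells and 68% for old against young. It recovered 37% for the interaction and 86% for Y30F against wild-type in old cells. At log2 2 it recovered 100%, 100%, 98% and 100%. False calls, in genes left unchanged, were 11 of 185, 10 of 178, 5 of 140 and 15 of 201 calls in the same order. The real groups differ in spread, so these shares are not the sensitivity of each comparison. Groups of 2 are too small for a formal test of outlying libraries, so single libraries were only left out in turn.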

Results

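The 12 libraries held between 19019175 and 39544798 reads counted in genes, and 26183 to 33436 genes had a count. Reads outside annotated genes made up 3.46% to 10.8% of a library, and reads that could belong to more than 1 gene 3.94% to 5.86%. The 10 highest genes took 5.69% to 12.6% of the counts. In a principal component analysis, 63.3% of the variance lay along the leading component and 25.2% along the next. Replicates of young cells differed more than those of old cells. Over genes with at least 20 counts, chi-square per degree of freedom between replicates was 36.2, 32.5 and 41.7 in young cells with the empty virus, wild-type MYOD and Y30F. In old cells it was 7.51, 4.55 and 2.57. All comparisons share 1 estimate of the spread. Those among old libraries were thus judged against a spread wider than their own, and those among young libraries against a narrower one.

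MYOD1 (ENSG00000129152), the gene carried by the MYOD viruses, was low with the empty virus, at 0.336 ± 0.204 CPM (SD, n = 2) in young cells and 0.417 ± 0.216 in old cells. With wild-type MYOD it reached 2644 ± 1268 CPM in young and 1790 ± 1234 CPM in old cells, and with Y30F 1511 ± 279.8 and 486 ± 59.5 CPM. The wild-type libraries differed within a group: 3541 and 1747 CPM in young cells, 918 and 2663 CPM in old cells. In old cells MYOD1 was lower with Y30F than with wild-type, at log2 −1.88 (SE 0.41, adjusted p = 0.0458). That call was lost with the stricter filter (adjusted p = 0.0505), with the replicate number as a block (0.0564) and in 3 of the 4 fits without a library (0.3 to 0.492), and without old wild-type library 2 the difference was −0.92. In young cells the difference was −0.81 (SE 0.40, adjusted p = 0.808), and −0.78 (adjusted p = 9.48e-07) without a filter. Removing the filter made 61 results of named genes pass and left 660 as they were. A call gained only in that setting carries little weight. The wild-type effect on MYOD1 differed between ages by −0.93 (SE 1.23, adjusted p = 0.606). Counts do not tell viral from endogenous MYOD1 RNA, and protein was not measured.

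Old cells were compared with young cells, both with the empty virus, to see how they differed without MYOD. The libraries of an age are not said to be separate cultures. Passage can therefore not be told apart from other differences between the cultures. Genes of cell division were lower in old cells. In the mitosis list 39 of 41 tested members fell and 0 rose (39 and 0 adjusted over the list alone); camera adjusted p = 9.24e-33. MKI67, found in the nuclei of cycling cells (ENSG00000148773), went from 60.5 ± 5.97 to 12.3 ± 0.266 CPM (log2 −2.30 (SE 0.13, adjusted p = 2.14e-07)), and CENPF, a kinetochore protein, fell by 2.09. In the DNA replication list 26 of 45 tested members fell and 1 rose (29 and 1 adjusted over the list alone), among them RRM2, a subunit of ribonucleotide reductase, at log2 −2.31 (SE 0.23, adjusted p = 1.94e-05); camera adjusted p = 3.83e-09, adjusted p = 0.424 with an estimated correlation. MYBL2, a cell cycle transcription factor, was among the 5 largest losses (−3.55 (SE 0.36, adjusted p = 1.69e-05)). LMNB1, the nuclear lamin whose loss is a known mark of senescent cells, went from 10.98 ± 0.224 to 2.97 ± 0.227 CPM (−1.89 (SE 0.15, adjusted p = 2.74e-06)). Of the E2F and pocket protein list 3 members rose and 8 fell, and CCND2, a D-type cyclin, rose to 131 ± 3.09 from 8.70 ± 0.521 CPM (3.91 (SE 0.12, adjusted p = 2.23e-09)). This list had no call (camera adjusted p = 0.65).

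Inhibitors of the cell cycle rose in part. CDKN2B, the p15 inhibitor, rose by log2 1.70 (SE 0.15, adjusted p = 5.71e-06) and CDKN2A (ENSG00000147889), which encodes p16 and ARF, by 1.04 (SE 0.24, adjusted p = 0.00712), from 4.28 ± 1.67 to 8.74 ± 1.99 CPM. The CDKN2A call was lost without old empty library 1 (0.79, adjusted p = 0.0685). CDKN1A, the p21 inhibitor, differed by 0.12 (SE 0.15, adjusted p = 0.557). Of the p53 target list, 9 of its 31 tested members rose and 1 fell (9 and 1 adjusted over the list alone), with ZMAT3 at 1.33 (SE 0.16, adjusted p = 7.67e-05) and RRM2B at 1.57 (SE 0.20, adjusted p = 0.000111); camera adjusted p = 0.0123, adjusted p = 0.211 with an estimated correlation. In the DNA damage list 17 of 46 tested members fell and 3 rose (19 and 4 adjusted over the list alone), and those that fell include the replication-linked CLSPN, EXO1 and FANCD2 (−1.90, −1.91 and −1.37); camera adjusted p = 0.0123, adjusted p = 0.675 with an estimated correlation.

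Secreted and matrix genes differed both ways between old and young cells. Of the senescence-associated secretion list, 16 of its 39 tested members rose and 11 fell (17 and 11 adjusted over the list alone). MMP10, a matrix metalloproteinase, and IGFBP3, a binding protein of insulin-like growth factors, rose by log2 3.83 (SE 0.23, adjusted p = 2.47e-07) and 2.14 (SE 0.15, adjusted p = 8.88e-07), whereas the chemokine CXCL12 was lower (−1.63 (SE 0.12, adjusted p = 1.68e-06)). The list had no call (camera adjusted p = 0.0501). The fibroblast matrix list had 9 higher and 8 lower of 35 tested (12 and 10 adjusted over the list alone), with TNC, the matrix protein tenascin C, at −2.78 (SE 0.16, adjusted p = 1.99e-07) (camera adjusted p = 0.67). The interferon list had 14 higher and 6 lower of 39 tested (16 and 7 adjusted over the list alone), among them IFI44 at 2.91 (SE 0.25, adjusted p = 4.55e-06); camera adjusted p = 0.0345, adjusted p = 0.679 with an estimated correlation. Its score was −1.01 and −1.94 in young empty libraries 1 and 2 against −0.804 and −0.762 in the old ones, so much of that gap rests on young empty library 2. Smooth muscle and TGF-beta genes counted 9 higher and 4 lower of 24 tested (10 and 7 adjusted over the list alone) (camera adjusted p = 0.25), and the heat shock list 6 higher and 5 lower of 30 tested (6 and 7 adjusted over the list alone) (camera adjusted p = 0.638).

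The largest gains in old cells were of HTR2A, a serotonin receptor (8.28 (SE 0.47, adjusted p = 1.91e-07)), and LGR5, the R-spondin receptor (7.34 (SE 0.33, adjusted p = 3.06e-08)). Also among them were FAM133A and DIRAS2, without reads in young empty libraries and at least 23.2-fold and 10.0-fold higher, and RRAGD, a GTPase of the lysosomal amino acid sensor (ratio 179, 95% interval 49.2 to 1480). TSPAN18, a tetraspanin (−4.91 (SE 0.34, adjusted p = 9.32e-07)), and WNT2, a Wnt ligand (−3.74 (SE 0.31, adjusted p = 4.07e-06)), were among the largest losses. HTR2A had few reads in young and TSPAN18 in old empty libraries, so their SE can be too small. HTR2A differed by 9.11 without young empty library 2, and TSPAN18 by −5.52 without old empty library 1. Some muscle genes were already higher in old cells without MYOD. In the myogenic regulator list 11 of its 35 tested members rose and 3 fell (11 and 3 adjusted over the list alone), with JAM2, an adhesion molecule, at 2.89 (SE 0.13, adjusted p = 3.06e-08); camera adjusted p = 0.0138, adjusted p = 0.11 with an estimated correlation.

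In all, 3461 genes were higher and 3106 lower in old cells, out of 22213. Scaled by total counts alone, 3010 were higher and 3549 lower, which turns the balance. Leaving out single libraries gave 1859 to 3926 and 1433 to 3889. The lowest came without old empty library 2, and without young empty library 1 they were 2156 and 1848. Without old empty library 1, 2070 genes were lower. A fit of the 4 empty libraries alone gave 2099 and 2059. The authors' deposited table lists as higher 1959 genes and as lower 1820, of which 3724 in total were called here with the same sign and 0 with the opposite sign. For MKI67 the authors' deposited table gives log2 −2.21 (adjusted p = 5.51e-27), for LMNB1 −1.73 and for CDKN2A 0.90 (adjusted p = 0.0222).

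Wild-type MYOD against the empty virus in young cells shows how far MYOD turned these fibroblasts towards muscle. Nearly the whole set of muscle genes came on. Of the sarcomere list, 44 of its 46 tested members rose and 0 fell (44 and 1 adjusted over the list alone), with a median of log2 8.41 (7.87 with genes without reads at their bound); camera adjusted p = 1.94e-66. MYH8, the perinatal myosin heavy chain, went from 0.104 ± 0.0384 to 1179 ± 229 CPM (13.43 (SE 0.28, adjusted p = 1.63e-12)), and CKM (ENSG00000104879), muscle creatine kinase, from 0.0846 ± 0.0655 to 471 ± 18.4 CPM. MYH8 had few reads with the empty virus at both ages, so the SE of its fold can be too small. MYOG (ENSG00000122180), the myogenin that drives terminal differentiation, reached 882 ± 158 CPM, a ratio of 21200 (95% interval 5860 to 175000) over the 2 reads with the empty virus. UNC45B, a myosin chaperone, and ACTN2, the sarcomeric actinin, had ratios of 10300 (2860 to 85400) and 11900 (4070 to 57700).

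The other muscle lists moved the same way. Of the myogenic regulators and fusion genes, 33 of its 35 tested members rose and 1 fell (33 and 1 adjusted over the list alone) (median 5.82, 5.52 at the bound; camera adjusted p = 1.22e-43), with MEF2C, a partner of MYOD, at 7.16 (SE 0.18, adjusted p = 1.00e-11). Of excitation-contraction coupling and synapse, 27 of its 30 tested members rose and 2 fell (27 and 2 adjusted over the list alone) (camera adjusted p = 3.08e-40), with STAC3, needed for calcium release, at 8.38 (SE 0.19, adjusted p = 3.73e-12) and the acetylcholine receptor subunit CHRNB1 at 6.06 (SE 0.15, adjusted p = 5.71e-12). Of muscle energy metabolism, 19 of its 23 tested members rose and 3 fell (19 and 3 adjusted over the list alone) (camera adjusted p = 9.87e-12), with ENO3, the muscle enolase, at 7.26 (SE 0.19, adjusted p = 1.01e-11). Among the largest gains, SMYD1, a muscle histone methyltransferase, was at least 8770-fold higher. UTS2R, TRIM72, DUSP13 and RXRG were at least 2130-fold, 1950-fold, 1720-fold and 1630-fold higher. The largest losses were of SLC38A11, OLR1 and OLFM4 (−7.33, −7.31 and −6.64, SE 0.22, 0.43 and 0.29). OLR1 had few reads with wild-type MYOD, and without young wild-type library 1 or 2 it differed by −6.49 and −8.45.

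**Figure D1:**
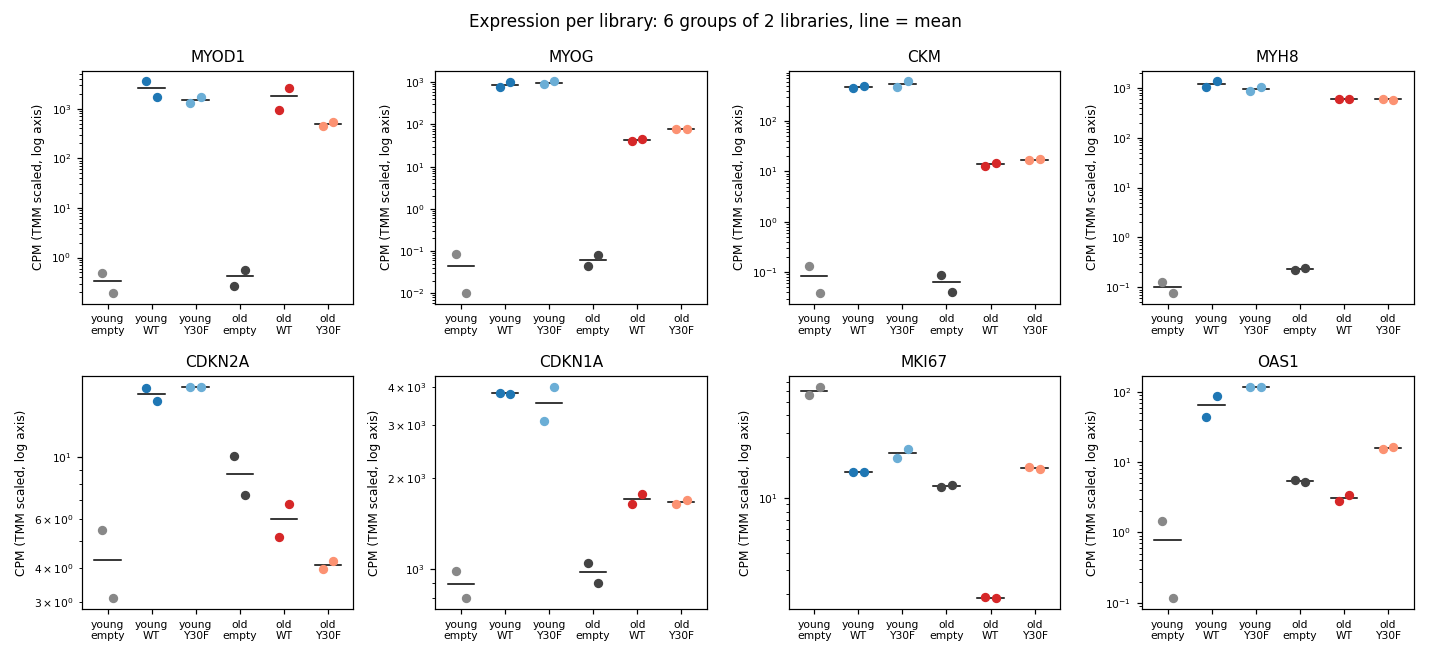
TMM-scaled CPM on a log axis for 8 genes in the 12 libraries, a point per library and a bar at the group mean, with 0 CPM drawn at 0.01. MYOG means were 882 CPM in young and 42.8 CPM in old cells with wild-type MYOD, and OAS1 means 65.2 and 3.09 CPM.

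Along with muscle genes, inhibitors of the cell cycle rose in young cells with wild-type MYOD. CDKN1A rose by log2 2.10 (SE 0.15, adjusted p = 9.48e-08) to 3831 ± 21.5 CPM, CDKN1C, the p57 inhibitor, by 7.35 (SE 0.42, adjusted p = 9.42e-09), and CDKN2A by 1.99 (SE 0.24, adjusted p = 1.07e-05). Of the p53 target list, 22 of its 31 tested members rose and 2 fell (22 and 2 adjusted over the list alone), with TP53I3 at 2.91 and BTG2 at 2.42; camera adjusted p = 0.000814, adjusted p = 0.066 with an estimated correlation. In the mitosis list 29 of 41 tested members fell and 2 rose (30 and 2 adjusted over the list alone), with MKI67 at −1.95 (SE 0.13, adjusted p = 4.40e-08); camera adjusted p = 0.000246, adjusted p = 0.292 with an estimated correlation. AURKA, a mitotic kinase, rose instead (3.22 (SE 0.17, adjusted p = 6.38e-09)). In the DNA damage list 32 of 46 tested members fell and 6 rose (33 and 6 adjusted over the list alone), among them the mismatch repair gene MSH6 (−1.78) and MRE11, a double-strand break nuclease (−2.57); camera adjusted p = 0.000543, adjusted p = 0.318 with an estimated correlation. The E2F and pocket protein list had 10 higher and 9 lower of 25 tested (10 and 9 adjusted over the list alone), and CCND3, a D-type cyclin of muscle differentiation, rose by 4.40 (SE 0.23, adjusted p = 4.59e-09) (camera adjusted p = 0.691). The DNA replication list had 5 higher and 20 lower of 45 tested (5 and 20 adjusted over the list alone) (camera adjusted p = 0.0826).

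Fibroblast programs went down in the same libraries. In the fibroblast matrix list 25 of 35 tested members fell and 6 rose (25 and 6 adjusted over the list alone), with FN1, fibronectin, at −2.92 (SE 0.12, adjusted p = 6.04e-10); camera adjusted p = 4.97e-06, adjusted p = 0.193 with an estimated correlation. In the smooth muscle and TGF-beta list 15 of 24 tested members fell and 6 rose (15 and 6 adjusted over the list alone), with the TGF-beta target CCN2 at −3.29 (SE 0.12, adjusted p = 1.31e-10) and calponin CNN1 at −3.47 (SE 0.16, adjusted p = 1.24e-09); camera adjusted p = 0.000867, and adjusted p = 0.0454 with an estimated correlation. In the senescence-associated secretion list 22 of 39 tested members fell and 7 rose (22 and 7 adjusted over the list alone), with the growth factor FGF2 at −4.50 (SE 0.25, adjusted p = 8.50e-09); camera adjusted p = 0.00187, adjusted p = 0.318 with an estimated correlation. The MYOD antagonists had 10 higher and 3 lower of 20 tested (10 and 3 adjusted over the list alone), HEYL, a Notch target, at 8.03 (SE 0.28, adjusted p = 9.95e-11) (camera adjusted p = 0.0753). Interferon genes rose. Of that list, 32 of its 39 tested members rose and 1 fell (32 and 1 adjusted over the list alone), with USP18, which restrains interferon signalling, at 5.87 (SE 0.24, adjusted p = 4.85e-10), and IFI27 going from 1.56 ± 0.750 to 74.6 ± 10.2 CPM; camera adjusted p = 8.82e-10, adjusted p = 0.318 with an estimated correlation. USP18 differed by 6.50 without young empty library 1. The heat shock list had 11 higher and 10 lower of 30 tested (11 and 10 adjusted over the list alone) (camera adjusted p = 0.85).

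In all, 7645 genes were higher and 7310 lower with wild-type MYOD in young cells. Of these, 4611 were lower by at least log2 1. A fit of only the groups compared gave 6282 higher and 5983 lower. Scaled by total counts alone, 6818 were higher and 8291 lower, which turns the balance. Scaling by total counts alone shifted the median of all genes by log2 −0.15 here, 0.21 in old cells with wild-type MYOD and 0.37 for their difference, and by −0.19 and 0.27 for Y30F in young and old cells.

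The same comparison in old cells shows what wild-type MYOD did at late passage. Muscle genes rose here as well. Of the sarcomere list, 40 of its 46 tested members rose and 1 fell (40 and 1 adjusted over the list alone) (median 5.23, 4.98 at the bound; camera adjusted p = 9.09e-41). MYH8 reached 599.8 ± 3.57 CPM (11.30 (SE 0.25, adjusted p = 1.07e-11)) and MYH3, the embryonic myosin heavy chain, 20.1 ± 0.370 from 3.90 ± 0.469 CPM (2.36 (SE 0.21, adjusted p = 6.81e-07)). MYOG reached 42.8 ± 3.31 CPM, a ratio of 677 (231 to 3290), and CKM 13.9 ± 1.20 CPM, a ratio of 220 (75.0 to 1070). Of the myogenic regulators, 29 of its 35 tested members rose and 3 fell (30 and 3 adjusted over the list alone) (camera adjusted p = 9.59e-24), with MEF2C at 6.57 (SE 0.18, adjusted p = 2.83e-11). Of excitation-contraction coupling and synapse, 27 of its 30 tested members rose and 2 fell (27 and 2 adjusted over the list alone) (camera adjusted p = 1.33e-28), and of muscle energy metabolism, 19 of its 23 tested members rose and 2 fell (19 and 2 adjusted over the list alone) (camera adjusted p = 4.13e-07). ADGRG5, FXYD6 and HJV, the hemojuvelin of iron control, were at least 553-fold, 421-fold and 398-fold higher. SHD had a ratio of 5620 (1010 to 222000). HTR2A, LGR5 and DKK1, a Wnt antagonist, had the largest losses (−6.97, −6.51 and −6.42, SE 0.41, 0.30 and 0.19), with HTR2A at −8.10 without old wild-type library 2.

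Cell cycle and fibroblast genes also moved in old cells. In the mitosis list 25 of 41 tested members fell and 6 rose (25 and 6 adjusted over the list alone); camera adjusted p = 0.0422, adjusted p = 0.57 with an estimated correlation. MKI67 went from 12.3 ± 0.266 to 1.89 ± 0.0259 CPM (−2.70 (SE 0.16, adjusted p = 1.64e-08)), while PTTG1, securin, and AURKA rose (5.13 (SE 0.26, adjusted p = 4.09e-09) and 2.97 (SE 0.18, adjusted p = 1.99e-08)). In the DNA damage list 30 of 46 tested members fell and 7 rose (31 and 7 adjusted over the list alone), and LIG4, a ligase of end joining, was among those that rose (1.92 (SE 0.16, adjusted p = 4.47e-07)); camera adjusted p = 0.0114, adjusted p = 0.49 with an estimated correlation. CDKN1A rose by 0.81 (SE 0.15, adjusted p = 0.000352), CDKN2B was lower (−1.57 (SE 0.15, adjusted p = 1.23e-06)) and CDKN2A differed by −0.54 (SE 0.24, adjusted p = 0.0624), a call gained without a filter (−0.53, adjusted p = 0.0274), in a fit of only the groups compared (−0.49, adjusted p = 0.0473) and without old empty library 2 (−0.77, adjusted p = 0.0312). ABL1, the kinase linked to this tyrosine, fell by 0.99 (SE 0.14, adjusted p = 3.22e-05). In the fibroblast matrix list 25 of 35 tested members fell and 2 rose (25 and 2 adjusted over the list alone), with FN1 at −3.90 (camera adjusted p = 8.57e-08, adjusted p = 0.145 with an estimated correlation). In the smooth muscle and TGF-beta list 17 of 24 tested members fell and 3 rose (18 and 3 adjusted over the list alone), with CCN2 at −5.09 (SE 0.13, adjusted p = 1.52e-11) (camera adjusted p = 2.66e-09). In the senescence-associated secretion list 19 of 39 tested members fell and 10 rose (20 and 10 adjusted over the list alone), with the chemokine CCL2 at −4.00 (SE 0.15, adjusted p = 3.43e-10) and INHBA, an activin subunit, at −4.95; camera adjusted p = 0.00036, adjusted p = 0.328 with an estimated correlation. The interferon list had 7 higher and 20 lower of 39 tested (8 and 20 adjusted over the list alone), XAF1 at −3.90 (SE 0.27, adjusted p = 8.04e-08) (camera adjusted p = 0.234). The p53 target list had 12 higher and 3 lower of 31 tested (12 and 3 adjusted over the list alone), TP53I3 at 3.70 (SE 0.14, adjusted p = 2.75e-10) (camera adjusted p = 0.223). Leukocyte markers had 5 higher and 0 lower of 6 tested (5 and 0 adjusted over the list alone) (camera adjusted p = 0.0128, adjusted p = 0.103 with an estimated correlation).

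In all, 7347 genes were higher and 6906 lower with wild-type MYOD in old cells, and 4122 of the latter by at least log2 1. Scaled by total counts alone, 8777 were higher and 5507 lower. The response of the same genes can be set beside that in young cells because the controls are separate. Both ages shared 5051 higher genes where independence would give 2529, and 4786 lower genes where it would give 2273. Of opposite sign were 457 and 445. Of 7644 genes higher in young cells, MYOD1 apart, 84.6% had the same sign in old cells, with a median of log2 1.52 in young and 1 in old cells. Picking genes by their call at an age favours a larger value at that age, and the 7346 genes higher in old cells had a median of 1.27 in young and 1.45 in old cells. Across genes called in young cells the slope of the old on the young response was 0.72 (0.624 to 0.755 without single libraries), and across genes called in old cells 0.826. Pearson's r across all genes was 0.794, and genes are not independent replicates.

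The interaction asks whether MYOD did less, or more, in old cells. Muscle genes responded less in old cells. In the sarcomere list the wild-type effect was smaller or more negative in old cells for 19 of 46 members and larger for 1 (19 and 1 adjusted over the list alone). Its median difference was log2 −1.999 (camera adjusted p = 2.60e-08), and −1.72 over the 29 members with more than 3 counts in every group. In the myogenic regulator list the effect was more negative in old cells for 18 of 35 and more positive for 1 (20 and 1 adjusted over the list alone; median −1.81, or −1.33 over 24 members; camera adjusted p = 2.60e-08). MYH3 differed by −4.39 (SE 0.31, adjusted p = 2.36e-06), DYSF, a membrane repair protein, by −3.36 (SE 0.20, adjusted p = 8.19e-07), and JAM2 by −3.08 (SE 0.17, adjusted p = 5.96e-07). With wild-type MYOD, JAM2 was at 59.4 and 69.2 CPM in young and 56.0 and 56.3 CPM in old libraries. Its difference lies in the empty-virus level, at 6.90 and 7.58 CPM in young and 54.2 and 53.2 CPM in old libraries. LDB3, a Z-disc protein, was 113 ± 26.6 CPM in young and 14.5 ± 0.0108 CPM in old cells with wild-type MYOD (−4.12 (SE 0.26, adjusted p = 1.16e-06)). MYOG differed by −4.95 (SE 1.31, adjusted p = 0.012) and CKM by −4.74 (SE 1.16, adjusted p = 0.00768). The MYOG value rests on 2 and 3 reads in the empty-virus groups and the CKM value on 3 reads in the old one. The MYOG call was lost without old empty library 2 (−4.48, adjusted p = 0.141) and the CKM call without old empty library 1 (−4.17, adjusted p = 0.161). Without young empty library 1 or 2 MYOG differed by −8.20 and −3.95 and CKM by −5.76 and −4.10. MYH8 (−2.13 (SE 0.62, adjusted p = 0.0199)) lost its call in 3 fits without a library (−2.21 to −1.79, adjusted p = 0.059 to 0.112). MEF2C did not pass (−0.59 (SE 0.28, adjusted p = 0.122)) but did without young empty library 1 (−0.89, adjusted p = 0.0398).

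The other muscle lists went the same way, with less support. Excitation-contraction coupling and synapse had 0 higher and 9 lower of 30 tested (0 and 9 adjusted over the list alone) (median −1.68, −1.26 over 18 members; camera adjusted p = 0.0145, adjusted p = 0.326 with an estimated correlation). Muscle energy metabolism had 2 higher and 8 lower of 23 tested (2 and 8 adjusted over the list alone) (median −0.81, −0.86 over 16 members; camera adjusted p = 0.0201, adjusted p = 0.0903 with an estimated correlation). A direct comparison took the 79 muscle genes that wild-type MYOD raised by at least log2 4 in young cells. With wild-type MYOD, 69 of them were lower in old than in young cells and 2 were higher, with a median of log2 −1.67. Picking genes by a large rise in young cells favours lower values in old cells.

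Of the 21 lists, interferon genes had the largest median difference between ages. Of that list, 34 of 39 tested members had a more negative wild-type effect in old cells and 0 a more positive one by edgeR, over all genes and adjusted over the list alone alike (median −3.38; camera adjusted p = 3.57e-36, adjusted p = 0.0853 with an estimated correlation). OAS1, an antiviral RNA sensor, went from 0.777 ± 0.937 to 65.2 ± 30.7 CPM in young cells, and from 5.41 ± 0.214 to 3.09 ± 0.428 CPM in old cells (−7.24 (SE 0.68, adjusted p = 1.73e-05)). Without young empty library 1 or 2 the OAS1 difference was −9.89 and −6.30. IFI44 went from 3.92 ± 1.37 to 32.9 ± 10.8 CPM and from 29.4 ± 1.73 to 10.4 ± 1.16 CPM. Cell cycle regulators differed too. CCND2 rose with MYOD in young cells and fell in old cells (difference −4.22 (SE 0.15, adjusted p = 1.21e-08)). The effects on CDKN2A, CDKN2B, CDKN1A and CDKN1C were more negative in old cells (−2.53, −2.20, −1.29 and −2.85, SE 0.34, 0.21, 0.21 and 0.53). In the p53 target list the effect was more negative for 12 of 31 and more positive for 2 (14 and 2 adjusted over the list alone; camera adjusted p = 0.00105, adjusted p = 0.0853 with an estimated correlation). Smooth muscle and TGF-beta genes had 1 higher and 12 lower of 24 tested (2 and 13 adjusted over the list alone) (camera adjusted p = 0.000155), and MYOD antagonists 0 higher and 12 lower of 20 tested (0 and 13 adjusted over the list alone), with SOX9 at −3.31 (SE 0.27, adjusted p = 7.06e-06) (camera adjusted p = 6.25e-06, adjusted p = 0.126 with an estimated correlation). Mitosis genes had 9 higher and 4 lower of 41 tested (9 and 5 adjusted over the list alone) and no call (camera adjusted p = 0.133); PTTG1 (3.46 (SE 0.33, adjusted p = 1.94e-05)) and CDC25C, a mitotic phosphatase (3.51 (SE 0.40, adjusted p = 6.96e-05)), had a more positive effect in old cells.

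Beyond these, PADI2, which converts arginine to citrulline in proteins, went from 1.42 ± 0.334 to 237 ± 6.79 CPM in young cells but from 60.1 ± 1.501 to 22.5 ± 0.859 CPM in old cells (−8.80 (SE 0.24, adjusted p = 7.11e-10)). PDK4, the pyruvate dehydrogenase kinase, was 0.0446 CPM in young and 17.0 ± 0.294 CPM in old cells with wild-type MYOD (5.91 (SE 0.43, adjusted p = 6.63e-06)), so its value rests on few reads. In all, the wild-type effect was more positive in old cells for 3136 genes and more negative for 4149. Scaled by total counts these became 5555 and 2347, or 70.3% positive in place of 43.0%, and no called gene changed sign. Without old empty library 1 or old wild-type library 1 the former count was 2005 or 2081, and with a log2 difference of at least 1 the counts were 2054 and 2504.

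**Figure D2:**
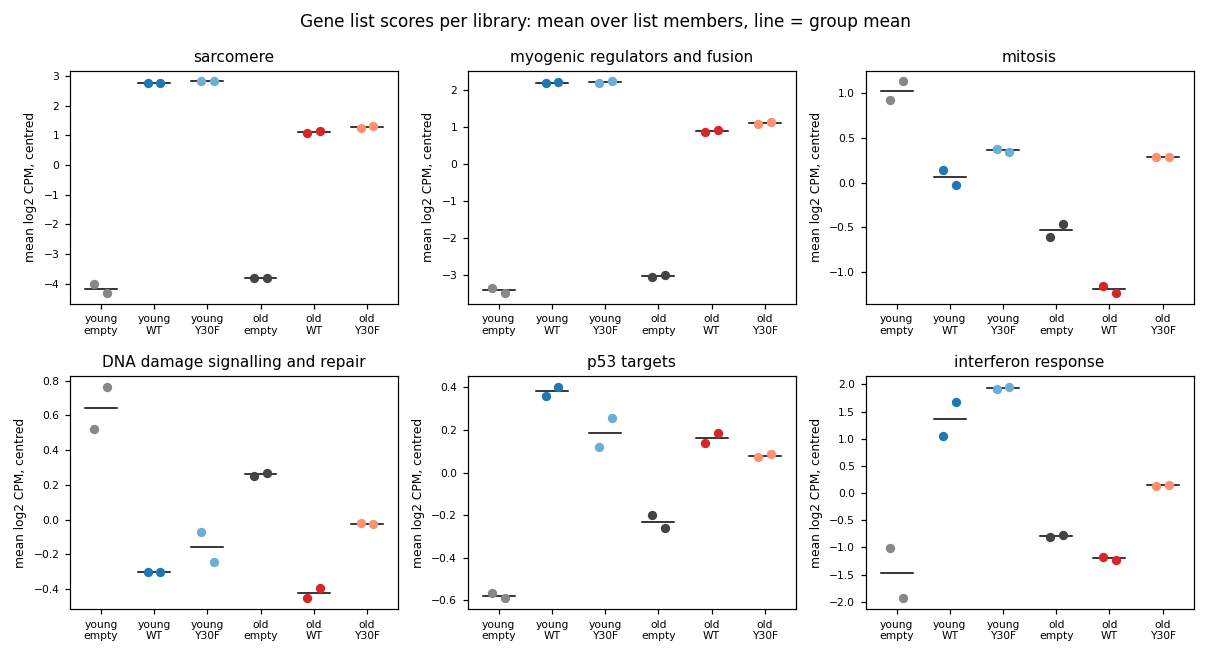
Scores of 6 gene lists (mean log2 CPM of the members, centred per gene) in the 12 libraries, a point per library and a bar at the group mean, by age and virus. The median difference of the wild-type effect between ages was log2 −3.38 for the interferon list and −1.999 for the sarcomere list.

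Y30F against the empty virus asks whether MYOD without this tyrosine still turns on muscle genes at each age. It did at both ages. In young cells, of the sarcomere list, 43 of its 46 tested members rose and 1 fell (43 and 1 adjusted over the list alone) (median 8.67, 8.17 at the bound; camera adjusted p = 4.85e-70), and of the myogenic regulator list 33 of its 35 tested members rose and 1 fell (33 and 1 adjusted over the list alone) (camera adjusted p = 5.74e-45). MYOG reached 983 ± 94.0 CPM, a ratio of 23800 (6580 to 196000), and SMYD1 was at least 9160-fold higher. In the interferon list 35 of its 39 tested members rose and 1 fell (36 and 1 adjusted over the list alone), with IFI27 at 6.15 (SE 0.24, adjusted p = 3.03e-10); camera adjusted p = 4.16e-14, adjusted p = 0.258 with an estimated correlation. In the mitosis list 25 of 41 tested members fell and 4 rose (25 and 4 adjusted over the list alone), with MKI67 at −1.52 (SE 0.13, adjusted p = 3.91e-07); camera adjusted p = 0.00686, adjusted p = 0.393 with an estimated correlation. FN1 fell by 2.35 and CDKN1A rose by 1.99 (SE 0.12 and 0.15). There were 7568 genes higher and 7320 lower, and 4519 lower by at least log2 1. A fit of only the groups compared gave 6312 higher and 5902 lower. Scaled by total counts alone, 6496 were higher and 8547 lower, which turns the balance.

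In old cells Y30F also raised muscle genes, and here mitosis genes rose with them. In the sarcomere list 39 of its 46 tested members rose and 2 fell (39 and 2 adjusted over the list alone) (median 5.67, 5.37 at the bound; camera adjusted p = 1.28e-48), and MYOG reached 79.6 ± 0.0207 CPM, a ratio of 1250 (429 to 6080). CKM had a ratio of 268 (91.3 to 1300). ADGRG5, HJV, SLC51B and CXCR4 were at least 652-fold, 524-fold, 420-fold and 372-fold higher. Of the mitosis list, 25 of its 41 tested members rose and 2 fell (26 and 2 adjusted over the list alone); camera adjusted p = 0.01, adjusted p = 0.489 with an estimated correlation. AURKA, PTTG1 and the kinesin KIF20A rose by 3.69, 4.71 and 1.73 (SE 0.18, 0.26 and 0.19). MKI67 rose by 0.42 (SE 0.13, adjusted p = 0.0138), a call lost in each of 4 fits without a library (adjusted p = 0.053 to 0.0871). The interferon list had 24 higher and 4 lower of 39 tested (25 and 4 adjusted over the list alone) (camera adjusted p = 0.01, adjusted p = 0.812 with an estimated correlation). In the fibroblast matrix list 28 of 35 tested members fell and 2 rose (28 and 2 adjusted over the list alone), with FN1 at −4.19 (SE 0.13, adjusted p = 7.75e-11); camera adjusted p = 5.96e-11, adjusted p = 0.0858 with an estimated correlation. There were 6749 genes higher and 6536 lower, 4298 and 3736 by at least log2 1. Scaled by total counts, 64.7% of the called genes were higher in place of 50.8%, and 5 called genes changed sign.

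Y30F against wild-type MYOD sets the constructs side by side. Their libraries also differed in mean MYOD1 RNA, and the viral preparations are not described. A difference need not come from the tyrosine. In young cells no gene differed by edgeR: 0 were higher and 0 lower of 22213, with 1444 at an unadjusted p under 0.05. DESeq2 called 60 higher and 5 lower, and edgeR without a filter 207 and 40. Without young wild-type library 2 the counts were 46 and 7, and without young Y30F library 2 they were 24 and 1. The median SE was log2 0.209, and a missing call does not show equal levels. MYOG differed by 0.16 (SE 0.16), MYH8 by −0.31 (SE 0.14) and the chemokine CCL2 by 0.94 (SE 0.14, adjusted p = 0.129), the last called by DESeq2, without a filter and without young Y30F library 2 (1.03, adjusted p = 0.0325). As whole lists, interferon genes lay higher with Y30F (median 0.50; camera adjusted p = 1.16e-22, adjusted p = 0.116 with an estimated correlation), and so did the fibroblast matrix (median 0.23; camera adjusted p = 1.28e-10, adjusted p = 0.0983 with an estimated correlation) and mitosis (0.30; camera adjusted p = 9.94e-10, adjusted p = 0.0983 with an estimated correlation). The p53 targets lay lower (−0.20; camera adjusted p = 4.45e-07, adjusted p = 0.0643 with an estimated correlation). None of the 21 lists held its call with an estimated correlation. The interferon score was 1.06 and 1.69 in wild-type libraries 1 and 2 against 1.92 and 1.96 with Y30F, so much of that gap rests on wild-type library 1. Among these 4 libraries the matrix score too was lowest in that one, at −0.323 against 0.097 and 0.148 with Y30F.

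In old cells, cell division and interferon genes were higher with Y30F than with wild-type MYOD. Of the mitosis list, 27 of its 41 tested members rose and 0 fell (39 and 0 adjusted over the list alone) (median 1.62; camera adjusted p = 2.02e-86). MKI67 was 1.89 ± 0.0259 CPM with wild-type and 16.5 ± 0.428 CPM with Y30F (3.13 (SE 0.16, adjusted p = 1.54e-06)). TOP2A, the topoisomerase of dividing cells, BUB1, a spindle checkpoint kinase, and TPX2, a spindle assembly factor, rose by 2.42, 2.47 and 1.63 (SE 0.19, 0.21 and 0.15). RRM2 rose by 1.80 (SE 0.25, adjusted p = 0.00379), and LMNB1 was 5.0 ± 0.0126 against 2.38 ± 0.123 CPM (1.07 (SE 0.16, adjusted p = 0.00548)). Of the interferon list, 18 of its 39 tested members rose and 0 fell (35 and 0 adjusted over the list alone) (median 1.38; camera adjusted p = 1.25e-60), with IFIT1, an antiviral RNA-binding protein, at 2.27 (SE 0.18, adjusted p = 0.000138). CCL2 rose by 1.73 (SE 0.15, adjusted p = 0.000166). Smooth muscle and TGF-beta genes had 1 higher and 4 lower of 24 tested (3 and 8 adjusted over the list alone), with TGFBI, a matrix protein induced by TGF-beta, at −1.01 (SE 0.11, adjusted p = 0.00121); camera adjusted p = 0.0107, adjusted p = 0.0909 with an estimated correlation.

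Few muscle genes were called between Y30F and wild-type MYOD in old cells. Of the myogenic regulator list, 2 of its 35 tested members rose and 0 fell (9 and 1 adjusted over the list alone) (median 0.22; camera adjusted p = 6.35e-06), among them MYOG at 0.90 (SE 0.16, adjusted p = 0.0183). Of the sarcomere list, 1 of its 46 tested members rose and 0 fell (3 and 0 adjusted over the list alone), namely MYH2, a fast myosin heavy chain, at 1.05 (SE 0.15, adjusted p = 0.0051); camera adjusted p = 0.000195, adjusted p = 0.0909 with an estimated correlation. Excitation-contraction coupling and synapse had 1 higher and 0 lower of 30 tested (2 and 0 adjusted over the list alone) (camera adjusted p = 0.0363, adjusted p = 0.36 with an estimated correlation), with CHRNG, the fetal acetylcholine receptor subunit, at 1.03 (SE 0.18, adjusted p = 0.0162). TNNT3, MYL4, SMYD1, CHRND and ATP2A1 did not pass (adjusted p = 0.055, 0.088, 0.0633, 0.0588 and 0.252) but did in a fit of these 4 libraries alone (0.70, 0.58, 0.46, 0.62 and 0.64) and without a filter, and all of them except ATP2A1 with DESeq2. CKM differed by 0.29 (SE 0.15, adjusted p = 0.381) and MYH8 by −0.04 (SE 0.14, adjusted p = 0.917). CDKN1A and CDKN2A differed by −0.03 and −0.55 (adjusted p = 0.938 and 0.298), and CKM and CDKN2A passed in a fit of these 4 libraries alone (adjusted p = 0.0274 and 0.0184). In the DNA damage list 1 of its 46 tested members rose and 0 fell (7 and 0 adjusted over the list alone) (median 0.32; camera adjusted p = 6.40e-08, adjusted p = 0.126 with an estimated correlation), namely RBBP8, which resects broken ends, at 0.86 (SE 0.17, adjusted p = 0.0269). In all, 192 genes were higher and 107 lower. Without single libraries the counts were 18 to 45 and 3 to 8, all 4 omissions moving them, and MYOG, CHRNG, MYH2, LMNB1 and RBBP8 lost their calls in each. RRM2 lost its call without either wild-type library (adjusted p = 0.0801 and 0.0846). MKI67, TOP2A, BUB1, TPX2, IFIT1, CCL2 and TGFBI kept theirs. Sizes moved little in these fits, with MYOG at 0.825 to 0.979, MYH2 at 1.004 to 1.098, CHRNG at 0.993 to 1.068 and RBBP8 at 0.829 to 0.886. A fit of these 4 libraries alone called 2923 and 2910, DESeq2 387 and 264, and no filter 515 and 428. Scaled by total counts 77.3% were higher in place of 64.2%.

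The last interaction asks whether the change from wild-type to Y30F differed between old and young cells. It did for 7 genes. MKI67 (2.69 (SE 0.20, adjusted p = 0.000212)), BUB1 (2.33 (SE 0.27, adjusted p = 0.0125)), TOP2A (2.06 (SE 0.25, adjusted p = 0.0125)), TRIP13, a checkpoint ATPase (1.72 (SE 0.24, adjusted p = 0.0367)), DLGAP5, a spindle protein (2.99 (SE 0.43, adjusted p = 0.0367)) and IFIT1 (1.74 (SE 0.25, adjusted p = 0.0367)) differed more in old cells. TGFBI differed the other way (−1.31 (SE 0.16, adjusted p = 0.0125)). Of the mitosis list 4 members passed over all genes and 26 adjusted over the list alone, each in the same direction (median 1.20; camera adjusted p = 1.74e-59). For myogenic regulators no member passed over all genes by edgeR and 1 did adjusted over the list alone (median 0.25; camera adjusted p = 4.02e-05), and smooth muscle and TGF-beta genes had 0 higher and 1 lower of 24 tested (2 and 7 adjusted over the list alone) (camera adjusted p = 3.36e-07). The fibroblast matrix list had 0 higher and 12 lower adjusted over the list alone (median −0.48; camera adjusted p = 1.67e-16, adjusted p = 0.05 with an estimated correlation), and the interferon list 15 and 0 (median 0.82; camera adjusted p = 9.74e-23, adjusted p = 0.165 with an estimated correlation). Without single libraries the counts were 1 to 20 higher and 0 to 7 lower. In those 8 fits MKI67 kept its call, whereas BUB1, TOP2A, TRIP13 and TGFBI lost theirs in 5, and IFIT1 and DLGAP5 in 6. IFIT1 also lost its call in a fit of only the groups compared (1.73, adjusted p = 0.079) and DLGAP5 with all libraries thinned to the smallest (2.89, adjusted p = 0.051). Without a filter there were 73 and 116 genes, and with DESeq2 39 and 43.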

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

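The tests against MYOD1 RNA, of a common factor, of library scaling, of an unusual library and of the spread between replicates were chosen only after the result was seen, and the share of strongly induced genes higher in old cells was set beforehand. What follows drew attention because the interaction test gave a different effect in old and young cells, or because reads outside the counted genes differed between groups.

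Muscle genes responded less to wild-type MYOD in old cells, with median interactions of log2 −1.999 for the sarcomere, −1.81 for myogenic regulators, −1.68 for excitation-contraction coupling and −0.81 for muscle energy metabolism. With an estimated correlation the last 2 lists lost their call (adjusted p = 0.326 and 0.0903). The slope of the muscle score on log2 MYOD1 within groups (0.028, SE 0.022) predicts a difference of −0.019 (95% interval −0.067 to 0.029) where −1.36 was observed. It rests on differences between replicates that the labels do not call separate cultures. It therefore does not decide on less MYOD1 RNA as a cause. Old wild-type library 2 had log2 MYOD1 of 11.4, above 10.8 in young wild-type library 2 and 10.4 and 10.7 with Y30F in young cells. Its muscle score was nevertheless 1.14, against 2.49, 2.49 and 2.53 in those libraries. These values go against MYOD1 RNA as the whole cause but rest on 1 old library. Fewer responding cells would lower all strongly induced genes by 1 factor. These are genes called at log2 4 or more in young cells, from under 1 CPM with the empty virus at both ages. Of 1230 such genes, however, 291, or 23.7%, were higher and 498 lower in old cells with wild-type MYOD. Choosing them in young cells favours lower values in old cells. Over the 79 induced muscle genes the log2 ratio had an SD of 1.38 against a median SE of 0.19. Scaling by total counts left the sarcomere median at −1.66. A share of the difference from fewer responding cells or from scaling stays open. So do a share from MYOD1 RNA, MYOD protein and the viral preparations, which the labels do not describe. A smaller reach of MYOD at late passage is a hypothesis that may be tested on other cells.

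In old cells mitosis genes were higher with Y30F than with wild-type MYOD, and the excess over young cells had a median of log2 1.20. Lower MYOD1 RNA with Y30F predicts −0.011 (95% interval −0.324 to 0.302) from the slope within groups, where the score differed by 1.48. That slope rests on replicates not said to be separate cultures, so it does not decide on MYOD1 RNA, which stays open. Leaving out any of the 4 libraries kept the median difference of the list between 1.57 and 1.68, while the number of members called fell from 27 to between 9 and 14 in those fits. The steady median argues against 1 unusual library as the whole cause. A viral preparation specific to a construct and the low number of libraries stay open. An effect of the tyrosine at late passage stays open too, and no test here separates it from a difference between viral preparations.

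As a list, interferon genes rose with wild-type MYOD in young cells and not in old cells. The median interaction was log2 −3.38 and the difference in the score −3.26. In old cells 7 of 39 members still rose and 20 fell. With an estimated correlation neither the rise in young cells (adjusted p = 0.318) nor the interaction (adjusted p = 0.0853) held its call. The largest difference between replicates of a group was 0.931, in young cells with the empty virus. The labels do not say whether replicates are separate cultures, so this spread decides nothing on the state of single cultures, which stays open. Virus dose read from MYOD1 RNA predicts 0.128 (95% interval −0.207 to 0.462) where old and young wild-type libraries differed by −2.57. This slope rests on the same replicates and decides nothing on dose, which stays open. Contaminants of a viral preparation stay open, since the labels name none and each construct at each age could have had its own. Passage itself, an age-dependent antiviral response for instance, may be a cause and was not tested. Old cells did show higher interferon scores with Y30F, at 0.133 and 0.155. Their scores were −0.804 and −0.762 with the empty virus and −1.178 and −1.225 with wild-type MYOD. The missing rise was thus that of the old wild-type libraries, though the rise with Y30F lost its camera call with an estimated correlation.

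By the same test 3136 genes had a more positive and 4149 a more negative effect of wild-type MYOD in old cells. Further lists with a difference were p53 targets (median log2 −0.56), smooth muscle and TGF-beta genes (−0.53) and MYOD antagonists (−1.09). With an estimated correlation the p53 targets and MYOD antagonists lost their call (adjusted p = 0.0853 and 0.126). Among called genes with a mean log2 CPM of at least 2, the largest positive differences were of PDK4 (log2 5.91), PDE7B (3.90), MGP (3.65), TMEM154 (3.64) and OLFM4 (3.49), and the largest negative ones of PADI2 (−8.80), CAPN6 (−8.71), HTR2A (−8.20), MYOM3 (−8.00) and OAS1 (−7.24). PDK4, CAPN6, HTR2A and MYOM3 have a group with hardly a read. HTR2A lost its call without young wild-type library 2, at −5.91 (adjusted p = 0.0628), and was −9.34 without old wild-type library 2. Without young empty library 1 or 2, MYOM3 was −10.40 and −7.07 and OAS1 −9.89 and −6.30. PDE7B was 4.72 without old empty library 1 and 2.95 without young empty library 2.

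Among muscle genes the differences were LDB3 −4.12, MYH3 −4.39, MYH8 −2.13, MYOG −4.95, CKM −4.74, JAM2 −3.08, DYSF −3.36, TMEM38A −2.80 and JPH2 −1.72. That of JAM2 lies in its higher level in old cells with the empty virus. Without single libraries MYOG ranged from −8.20 to −3.95 and CKM from −5.76 to −4.10, each losing its call in 1 such fit, and MYH8 lost its call in 3 (−2.21 to −1.79). In the cell cycle the differences were PCNA −0.88, MCM3 −1.06, PTTG1 3.46, CDC25C 3.51, CDC6 1.13, MKI67 −0.75, HMGB2 0.85, CCND2 −4.22 and CCND3 −2.46. Of these, MKI67 lost its call with total counts (−0.38, adjusted p = 0.178) and without either old wild-type library (−0.78 and −0.75, adjusted p = 0.0518 and 0.0635), and MCM3 with total counts (−0.70, adjusted p = 0.0609). CDC6 lost it without old empty library 1 (1.03, adjusted p = 0.0655) or old wild-type library 1 (1.085, adjusted p = 0.0521), and HMGB2 without old empty library 1 (0.74, adjusted p = 0.0686). Among inhibitors the differences were CDKN1A −1.29, CDKN2A −2.53, CDKN2B −2.20 and CDKN1C −2.85. For damage and p53 genes they were CLSPN 3.12, XRCC4 −1.72, ABL1 −0.86, GADD45A −1.71 and BTG2 −1.61. For secreted, matrix and TGF-beta genes they were PLAT −2.29, IGFBP3 −2.31, COL6A3 −1.94, SPARC −1.11, CCN2 −1.79 and LTBP1 −1.72. The rest were BHLHE40 −2.70, SOX9 −3.31, IFI27 −5.45 (−6.03 without young empty library 1), IFI44 −4.57, HSP90AA1 1.16 and HSPE1 1.16.

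The change from wild-type MYOD to Y30F was more positive in old cells for 6 genes and more negative for 1: MKI67 (2.69), BUB1 (2.33), TOP2A (2.06), DLGAP5 (2.99), IFIT1 (1.74), TRIP13 (1.72) and TGFBI (−1.31). In 8 fits without a library MKI67 kept its call, and each of the other 6 lost it in 5 or 6 fits. Lists with a difference by camera, besides mitosis, were the sarcomere (median 0.16), myogenic regulators (0.25), DNA replication (0.23), E2F and pocket proteins (0.19), DNA damage (0.21), p53 targets (0.13), senescence-associated secretion (−0.27), fibroblast matrix (−0.48), smooth muscle and TGF-beta (−0.26) and interferon (0.82). Of these, and with mitosis, only myogenic regulators, smooth muscle and TGF-beta and mitosis had adjusted p under 0.05 with an estimated correlation, at 0.0152, 0.0152 and 0.00882.

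Outside the counted genes, reads that could belong to more than 1 gene made up 5.67% in the 4 young MYOD libraries against 4.45% in the 2 with the empty virus, and 4.82% against 4.03% in old cells. Reads without a gene were 10.4% in old MYOD libraries against 9.05% with the empty virus. In young cells they were 4.77% (SD 1.14, n = 4) against 7.94% (SD 3.46, n = 2). The empty-virus libraries there had 5.49% and 10.4%, and the former lies within the range of the MYOD libraries (3.46% to 5.76%), so this gap rests on 1 library.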

How the results depend on the processing

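No alternative in this part was added after the results were seen. No result changed its direction past the threshold, and where a cause is not named it was not tested. Of the 18 counts, RLE size factors, the stricter filter and thinning kept each within 1.5 times its value. With an absolute log2 fold change of at least 1, a demand that itself lowers counts, old against young gave 1524 and 1146 genes higher and lower, the wild-type interaction 2054 and 2504, Y30F against empty in old cells 4298 and 3736, and Y30F against wild-type in old cells 110 and 45. Lower genes were then 4611 and 4122 for wild-type MYOD in young and old cells and 4519 for Y30F in young cells. Total counts as the only scaling gave 5555 and 2347 for the wild-type interaction. A fit of only the groups compared gave 2099 and 2059 for old against young, 2923 and 2910 for Y30F against wild-type in old cells, and 2 lower for the Y30F interaction, as did the replicate block. Without a filter, Y30F against wild-type gave 207 and 40 in young cells, 515 and 428 in old cells and 73 and 116 for their interaction; DESeq2 gave 60 and 5, 387 and 264, and 39 and 43. The slope over genes called in old cells was 0.826.

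Leaving out single libraries, with a lone library assumed to vary like the other groups, gave 1859 to 3926 and 1433 to 3889 for old against young, and 2005 to 3488 higher for the wild-type interaction. Y30F against wild-type gave 0 to 46 and 0 to 7 in young cells, 18 to 45 and 3 to 8 in old cells, and 1 to 20 and 0 to 7 for the interaction. The slope ranged from 0.624 to 0.755. Of 189 list results, 67 lost their call with an estimated correlation and 21 with fry, which gained 39, while total counts changed none and the block added 1. Of the named genes' values without single libraries 3318 stayed on their side of the threshold, 177 lost a call and 17 gained one. DESeq2 kept 678 and added 38. In the 15 pairs of groups the deviations of libraries with the same number correlated between −0.192 and 0.325. The highest values were 0.325 for wild-type MYOD with Y30F in young cells and 0.231 for the empty virus in young and old cells. Whether the numbers pair some of these libraries is therefore open, and a block gives all groups the same replicate effect.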

Other observations

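Markers of other cell types also moved, and the genes named here were chosen after their values were seen. With wild-type MYOD in old cells the leukocyte list had 5 higher and 0 lower of 6 tested (5 and 0 adjusted over the list alone), with CORO1A, an actin regulator of blood cells, going from 0.339 to 15.6 CPM and LAPTM5, a lysosomal protein of blood cells, from 0.171 to 5.73 CPM. In young cells it had 4 higher and 0 lower of 6 tested (4 and 0 adjusted over the list alone) (camera adjusted p = 0.0867). The neuronal list had 11 higher and 2 lower of 15 tested (11 and 2 adjusted over the list alone) with wild-type MYOD in young cells (camera adjusted p = 0.00593, adjusted p = 0.066 with an estimated correlation) and 10 higher and 3 lower of 15 tested (10 and 3 adjusted over the list alone) in old cells (camera adjusted p = 0.0735). It had 6 higher and 1 lower of 15 tested (7 and 1 adjusted over the list alone) in old against young cells (camera adjusted p = 0.000322, adjusted p = 0.0776 with an estimated correlation), with SYT1, a synaptic vesicle protein, at 3.93 (SE 0.20, adjusted p = 6.05e-08). The melanocyte and Schwann list had 1 higher and 2 lower of 6 tested (1 and 2 adjusted over the list alone) in young and 3 higher and 0 lower of 6 tested (3 and 0 adjusted over the list alone) in old cells (camera adjusted p = 0.427 and camera adjusted p = 0.147), and its member ERBB3, a neuregulin receptor, reached 144 and 58.1 CPM from 10.5 and 3.35. The endothelial list had 2 higher and 1 lower of 7 tested (2 and 1 adjusted over the list alone) in young and 4 higher and 1 lower of 7 tested (4 and 2 adjusted over the list alone) in old cells (camera adjusted p = 0.61 and camera adjusted p = 0.805), with CLDN5, a tight junction protein, at 272 and 8.39 CPM. The keratinocyte list had 4 higher and 2 lower of 7 tested (4 and 2 adjusted over the list alone) and 3 higher and 1 lower of 7 tested (3 and 1 adjusted over the list alone) (camera adjusted p = 0.204 and camera adjusted p = 0.971), and the adipocyte list 3 higher and 2 lower of 6 tested (3 and 2 adjusted over the list alone) and 2 higher and 1 lower of 6 tested (2 and 1 adjusted over the list alone) (camera adjusted p = 0.171 and camera adjusted p = 0.595). CD36, a fatty acid carrier that muscle cells also express, went from 1.70 to 50.04 CPM in young cells and was 93.2 CPM in old cells with the empty virus.

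Within the mitosis list, the 2 members that rose with wild-type MYOD in young cells were AURKA and PTTG1. In old cells 6 members rose, among them AURKA, PTTG1, CDC25C and KIF20A (2.97, 5.13, 2.89 and 1.24). AURKA went from 12.1 ± 1.62 to 113 ± 23.6 CPM with wild-type MYOD in young cells and from 6.88 ± 0.122 to 53.9 ± 3.57 CPM in old cells. PTTG1 went from 10.2 ± 1.28 to 32.2 ± 13.3 CPM and from 2.39 ± 0.0152 to 83.8 ± 3.80 CPM, while MKI67 fell by 1.95 and 2.70 on the log2 scale. Among D-type cyclins, CCND2 was 131 ± 3.09 CPM in old cells with the empty virus and 58.2 ± 0.261 CPM with wild-type MYOD. IL6, a cytokine of senescent cells, went from 9.37 ± 2.02 to 2.43 ± 0.116 CPM in young cells and from 1.25 ± 0.100 to 2.97 ± 0.266 CPM in old cells (interaction 3.19 (SE 0.36, adjusted p = 5.78e-05)).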
